A study of Mus musculus with 288 samples.

How the data were processed

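Gene expression was measured on 288 Affymetrix arrays of mouse RNA, 24 for each of 12 tissues. Per the labels' protocols, C57/BL6 mice spent 1 week in a cycle of 12 h light and 12 h dark and were then moved to constant darkness, RNA was extracted with Trizol and columns, and the RNA of 3 mice was pooled for each organ and time. The labels place the arrays of each tissue every 2 h from circadian time (CT) 18 to CT64. Per the submitters' processing notes, Affymetrix Expression Console and GCRMA made the values. Neither a version nor the order of the steps is stated there. The deposited unit is intensity on a linear scale, 1 value per probe set and array, from 6.9 to 45307.8. Array medians lay between 95.2 and 106.6 in every tissue, while the spread of the values was alike within a tissue and differed between tissues, so the authors' normalization appears to have been done for each tissue apart. Each wave was therefore fitted within its own tissue, and levels were compared between tissues only for marker genes and, for the sign of the difference alone, in 1 test of brown adipose against skeletal muscle, both of which this normalization can affect.

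The intensities were taken to the log2 scale with no pseudocount, since no value was 0 or missing. The tests had been planned for log2 values, which this step supplied. Of 35556 probe sets, 21789 carried 1 gene symbol, 1621 carried several and 12146 carried none in the annotation used here. Probe sets with 1 symbol were used, and a gene with more than 1 of them (999 genes) was represented by the one with the highest mean over all arrays, which gave 19938 genes. Chromosome positions come from the RefSeq table of mouse build GRCm38.p6, in which 21698 of the gene identifiers were found and 91 were not. No gene was left out for low intensity. The other 13767 probe sets were tested separately.

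Each tissue had 1 array per time point and no replicates. The p-values of the fits therefore measure the spread of pools around a fitted wave, and the number of arrays limits the precision. The sign-flip test of clock timing measures the spread over clock genes instead, and the Fisher exact test of lists compares counts of genes. In neither is the pool the unit, and genes are not independent of each other. For each tissue, a wave with a period of 24 h (cosine and sine) was fitted to the 24 arrays with limma 3.58.1, and both coefficients were tested together with the moderated F test (trend on mean expression). P-values were adjusted by the method of Benjamini and Hochberg over all genes of a tissue, and a gene with an adjusted p under 0.05 is called rhythmic. Wave size is the fitted peak-to-trough fold with its 95% interval, and peak time is given with its standard error (SE) by the delta method. Difference in rhythm between tissues was tested with a moderated F test of 22 interaction coefficients in 1 fit to all 288 arrays, with the matching contrasts for each pair of tissues. Waves of 12 h were tested in a model that also held the 24 h and 8 h pairs, and straight trends over the 2 days in a model that held the 24 h pair. Clock timing was compared by the circular difference of each of 12 core clock genes from its mean over 12 tissues, with an exact two-sided sign-flip test, adjusted over the tissues.

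Before the data were examined, 27 lists of genes by function and 29 lists of cell type markers were fixed, with 657 members of which 602 were measured. Some genes belong to more than 1 function list, such as Per1 and Tsc22d3, which are in the glucocorticoid response and a clock list. The sources of the lists were not recorded, so members known from earlier studies of daily expression may be among them. For each function list and tissue, rhythmic members were counted against all other genes with a two-sided Fisher exact test, adjusted over all 324 pairs of list and tissue. The mean profile of a list was tested with 100000 shuffles of the time points, for which the smallest p that shuffles can give is 1e-05, or 0.00014 after adjustment. Marker means per array were used to find arrays that stand apart, defined by a list mean over 5 scaled median absolute deviations and 1 log2 unit from the tissue median, or by a median correlation to the other arrays more than 5 such deviations and 0.003 below that median.

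The genes named in the text were chosen by a rule fixed in advance. It takes every measured gene of the core clock and clock output lists. For each tissue it takes the 4 genes with the largest fold among rhythmic genes above the tissue median whose peaks on the 2 days lay within 4 h, outside the clock lists and without predicted or clone names. It adds the 12 genes rhythmic in the most tissues, up to 4 members of each function list in the tissue with most rhythmic members, 8 genes with peaks at least 10 h apart in a pair of tissues, and 4 genes each for the 12 h waves and the trends. The 8 were rhythmic in both tissues of the pair and passed the test of difference for it.

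Alternatives planned in advance were a rank test of the JTK type over 12 phases, only genes above the tissue median, all probe sets, quantile normalization within a tissue, a straight line or the 12 h pair as covariates, array weights, leaving out each array or clock gene in turn, the time point as a replicate block, a spread estimated per tissue, and 10000 random lists matched on mean expression. Leaving out the arrays that stand apart, and adding the mean of 1 marker list as a covariate in 6 tissues, were chosen after seeing the data, as were leaving a named gene that is itself a marker out of its covariate and a timing comparison restricted to rhythmic clock genes. Counts were compared with those from 100 random orders of the time points, and the interaction count with 100 shuffles of the tissue labels.

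The tests were also tested on simulated data with the means and spreads of each tissue and 200 changed genes. Waves of 1.25-fold were recovered at rates from 34.3% in white adipose to 98.6% in cerebellum, with 90.6% in hypothalamus and 71.6% in liver. For waves of 1.5-fold the rates ran from 88.1% in adrenal gland to 100% in 4 tissues, and for 2-fold waves from 91.2% in white adipose to 100%. Between 4 and 14 unchanged genes were called per tissue. The noise was drawn for each gene apart, without variation shared by the genes of an array. False calls in the data can therefore be more. Random orders of the real time points in adrenal gland gave a median of 0 genes but as many as 964. For 12 h waves of 1.25-fold the recovery ran from 40.3% in skeletal muscle to 97.2% in cerebellum, and for trends of that size from 24.3% in white adipose to 90.1% in cerebellum. The interaction test, which uses 1 pooled spread, recovered 44.3%, 92.1% and 97.4% of genes with waves of 1.25-, 1.5- and 2-fold in 1 tissue, and called 216 unchanged genes. The fits were run in R 4.3.3, and the lists, permutations and figures in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.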

Results

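RNA from 12 mouse tissues was followed over 2 days of constant darkness: adrenal gland, aorta, brainstem, brown adipose, cerebellum, heart, hypothalamus, kidney, liver, lung, skeletal muscle and white adipose. Each tissue had 24 arrays, 1 for every 2 h from CT18 to CT64, where circadian time (CT) counts hours from the start of the subjective day, and each array held the pooled RNA of 3 mice. The series was made as an atlas of daily gene expression, so the comparisons ask which genes cycle in which tissue, when they peak, and which rhythms tissues share. Values are the authors' processed intensities on the log2 scale for 19938 genes. There were no replicates at a time point, and n = 24 arrays holds for every value within a tissue. The lowest median correlation of an array to the others of its tissue was 0.96 in white adipose at CT64 and in adrenal gland at CT50, against 0.998 in cerebellum at CT24. Markers of the labelled tissue were highest where the labels put them, such as hepatocyte markers in liver (mean log2 13.50, SD 0.03) and kidney tubule markers in kidney (12.12, SD 0.02).

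The genes of the clock itself cycled in all 12 tissues. Arntl, which encodes the activator BMAL1 of the core clock loop (probe set 10556463, chromosome 7 from 113178471 to 113314126), was rhythmic in all 12 with a mean peak at CT22.7. Its peak-to-trough fold ran from 1.23 (95% interval 1.16 to 1.32) in hypothalamus to 12.1 (8.92 to 16.5) in liver. Nr1d1, encoding the repressor of Arntl known as REV-ERB alpha (probe set 10390691, chromosome 11 from 98767932 to 98775377), peaked later, at a mean of CT7.09, with folds from 1.67 in hypothalamus to 21.97 (16.3 to 29.6) in lung. Dbp, a transcription factor driven directly by the clock (probe set 10553092, chromosome 7 from 45705100 to 45710203), peaked at CT9.73 and reached 14.8-fold (11.5 to 19.1) in lung. The period repressors followed each other, Per1 at CT10.3, Per3 at CT11.3 and Per2 at CT13.1, and the cryptochrome repressor Cry1 peaked later still, at CT17.4.

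**Figure D1:**
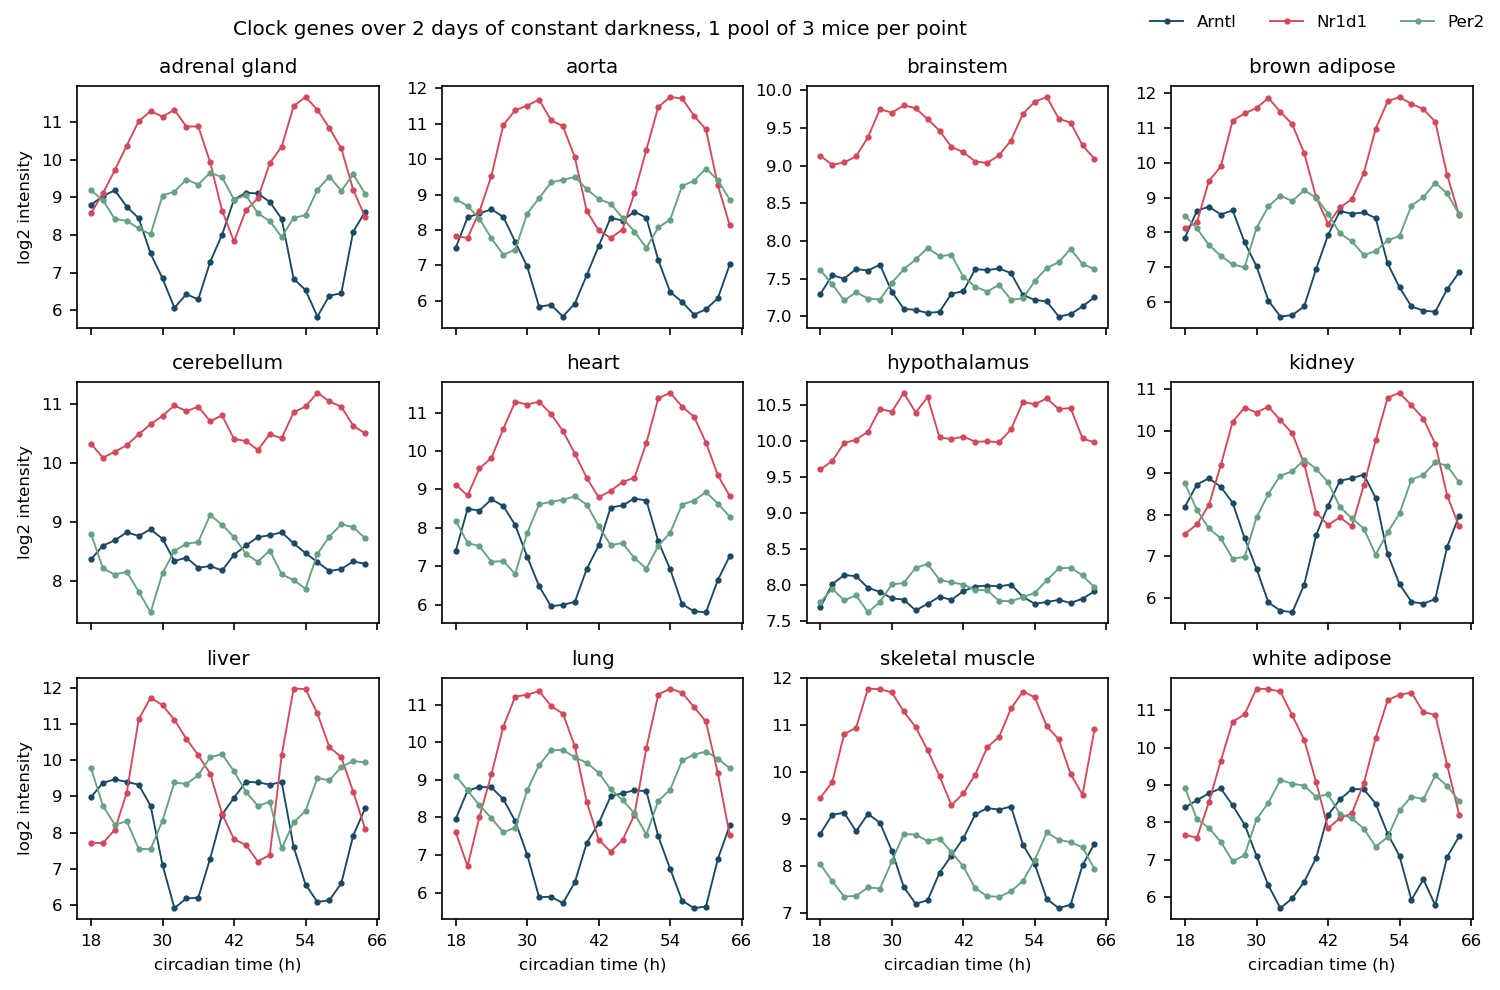
Log2 intensity of Arntl, Nr1d1 and Per2 against circadian time in hours, 1 panel per tissue, each point 1 array of RNA pooled from 3 mice. Nr1d1 peaks after Arntl in all 12 panels, by 5.85 h in skeletal muscle and by 7.58 h (heart) to 9.38 h (adrenal gland) elsewhere, with the flattest waves in brainstem, cerebellum and hypothalamus.

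All 12 measured core clock genes were rhythmic in aorta, cerebellum, heart, kidney, liver, lung and skeletal muscle, 11 in adrenal gland, brown adipose and white adipose, 10 in brainstem and 8 in hypothalamus. Adjusted over the list alone, the counts were 12 in adrenal gland, brainstem and white adipose and 11 in brown adipose and hypothalamus, with no change elsewhere. The Fisher exact test against all other genes gave adjusted p-values from 4.90e-14 in aorta to 1.19e-06 in liver. Clock, the partner of BMAL1, was rhythmic in 11 tissues with a largest fold of 2.13 (1.88 to 2.42) in liver. In hypothalamus, Cry1 had a fold of 1.08 (1.02 to 1.16, adjusted p = 0.299) and Clock 1.09 (1.03 to 1.16, adjusted p = 0.194), and neither passed. The repressor Bhlhe40 passed in 7 tissues, while its paralog Bhlhe41 passed in 12. Among the 12 clock output genes, 11 were rhythmic in adrenal gland, brown adipose, heart, liver and lung and 4 in hypothalamus (7 adjusted over the list alone, adjusted p = 0.000242). Nfil3, a repressor of the genes that Dbp activates, peaked at CT21.0 and reached 4.09-fold (3.11 to 5.39) in liver. Wee1, a kinase that delays mitosis, peaked at CT13.4 and reached 4.55-fold (3.22 to 6.43) in liver. Other output genes passed in fewer tissues, Leo1 in 10, Nampt in 8, Pdzrn3 in 4 and Klf10 in 2. Pdzrn3 peaked from CT11.8 in adrenal gland to CT1.96 in lung. In the rank test Pdzrn3 missed in brown adipose (adjusted p = 0.295) and heart (0.0721), and Klf10 in skeletal muscle (0.223). The median fold of the core clock genes was 4.06 in liver and 3.49 in aorta, against 1.41 in cerebellum, 1.28 in brainstem and 1.26 in hypothalamus. The difference in rhythm between tissues passed for Arntl (adjusted p = 3.17e-74), Nr1d1 (2.9e-59), Dbp (4.58e-51) and Cry1 (9.64e-38), and most weakly for Per1 among these (0.00405). In skeletal muscle the calls for Bhlhe40, Bhlhe41, Cry1 and Cry2 were lost with the lymphocyte marker mean as a covariate (adjusted p from 0.0637 to 0.129), with folds of 1.38, 1.41, 1.19 and 1.34 against 1.55, 1.59, 1.19 and 1.55 without it. That mean was raised mainly in the subjective night, as given below, so it can take up part of a true wave. The fold of Cry1 did not change, and these losses do not by themselves show lymphocyte RNA. Other calls were lost in the rank test: Clock, Cry1 and Bhlhe41 in brainstem (0.0794, 0.18 and 0.199), Cry1 in cerebellum (0.0629), Cry2 in white adipose (0.126) and Bhlhe40 in aorta (0.14), liver (0.11) and skeletal muscle (0.0514). The count of 12 in aorta and liver rests on Bhlhe40, which also missed there with a straight line as covariate (0.0762 and 0.105), and without the arrays that stood apart Clock missed in brainstem (0.0867), Cry2 in adrenal gland (0.0613) and white adipose (0.0866) and Bhlhe40 in aorta (0.055).

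Peak times of the clock genes were later in cerebellum, and earlier in adrenal gland and lung, than the mean of the 12 tissues. In cerebellum 11 of 12 core clock genes peaked after their 12-tissue mean, by 1.39 h on average (SD 0.731 h, adjusted p = 0.0117, exact sign-flip test), and Arntl peaked at CT0.922 there (SE 0.278 h). In adrenal gland 2 of 12 were later, the mean offset was -0.813 h (SD 0.703 h, adjusted p = 0.0176), and Arntl peaked at CT20.9 (SE 0.193 h). In lung 1 of 12 was later, with an offset of -0.297 h (SD 0.344 h, adjusted p = 0.0293). In skeletal muscle Nr1d1 peaked at CT4.54 and Per2 at CT11.3, the earliest of any tissue for both, but the mean offset of -1.13 h, the earliest of the 12 tissues, did not pass (adjusted p = 0.0762). Offsets of the other 8 tissues lay between -0.702 h in hypothalamus and 0.504 h in brown adipose and did not pass. Lung lost its call when any of 8 genes was left out (adjusted p up to 0.0586), and skeletal muscle passed without Clock (-1.35 h, adjusted p = 0.0352) or without Cry1 (-1.36 h, adjusted p = 0.0313). Clock genes drive each other, so the 12 are not independent of each other.

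Liver had the most rhythmic genes, 5343, of which 634 exceeded a fold of 1.5. Rgs16, which ends signalling by G proteins, varied 8.13-fold (5.12 to 12.9) with its peak at CT8.97 (SE 0.410 h, adjusted p = 4.70e-07). Chka, a choline kinase that starts phosphatidylcholine synthesis, varied 6.37-fold (5.15 to 7.87), Tubb2a, a tubulin, 5.57-fold (4.25 to 7.31), and Pdk4, a kinase that shuts off pyruvate oxidation, 5.33-fold (3.76 to 7.54), with peaks from CT21.7 to CT21.8. Cholesterol synthesis cycled almost as a whole, with 15 of 16 genes rhythmic (16 adjusted over the list alone, adjusted p = 3.06e-07). Hmgcs1, which makes the precursor of cholesterol, varied 1.96-fold with a peak at CT1.36, and Mvd and Lss, later enzymes of the pathway, 1.71- and 1.62-fold with peaks at CT20.6 and CT20.5. Fatty acid synthesis had 14 of 16 genes rhythmic (14 adjusted over the list alone, adjusted p = 4.96e-06), among them the elongases Elovl3 (4.66-fold, peak CT23.2) and Elovl6 (1.94-fold, peak CT13.7). In glucose and glycogen metabolism 10 of 17 were rhythmic (11 adjusted over the list alone, adjusted p = 0.0175), including the glycogen targeting subunit Ppp1r3c (4.66-fold), the glycolytic regulator Pfkfb3 (3.79-fold, peak CT10.2) and the glucose transporter Slc2a2 (1.53-fold, peak CT10.7). In bile acid synthesis and transport 7 of 10 were rhythmic (7 adjusted over the list alone, adjusted p = 0.0175), among them the export pump Abcb11 (1.475-fold, peak CT0.482) and Cyp8b1, which sets cholic acid production (1.73-fold). In xenobiotic metabolism 10 of 15 were rhythmic (10 adjusted over the list alone, adjusted p = 0.00585), with Alas1, the first enzyme of heme synthesis, at 2.06-fold and a peak at CT12.1. Against random lists matched on mean expression, the glucose, bile acid and xenobiotic lists did not pass in liver (adjusted p = 0.567, 0.947 and 0.86), and the glucose and bile acid lists also missed without the array at CT34 (0.0625 and 0.0679). Without that array, which stood apart by its correlation of 0.98 to the others, 5318 genes were rhythmic.

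Kidney had 5147 rhythmic genes, 175 of them above 1.5-fold. Nat8f5, an acetyltransferase family member, varied 3.26-fold (2.82 to 3.77) with its peak at CT14.4. Slc16a1, a transporter of lactate and other monocarboxylates, varied 3.25-fold (2.92 to 3.61, peak CT22.1, adjusted p = 5.49e-15), Ypel2 2.83-fold (2.51 to 3.19, peak CT21.1), and Sdf2l1, a chaperone partner of the endoplasmic reticulum, 2.81-fold (2.27 to 3.48, peak CT19.3). All 15 endoplasmic reticulum stress genes were rhythmic (15 adjusted over the list alone, adjusted p = 1.92e-08), among them the chaperone Hsp90b1 (1.58-fold, peak CT20.7) and the disulfide isomerase Pdia6 (1.59-fold, peak CT20.6). Of 16 heat shock genes 14 were rhythmic (14 adjusted over the list alone, adjusted p = 3.08e-06), such as Hsp90aa1 (1.59-fold, peak CT20.1) and its cochaperone Chordc1 (1.67-fold, peak CT18.4). In renal transport 10 of 16 were rhythmic (11 adjusted over the list alone, adjusted p = 0.00813), with the vasopressin receptor Avpr1a at 2.24-fold (peak CT22.2), the sodium-proton exchanger Slc9a3 at 1.35-fold (peak CT7.94) and the water channel Aqp3 at 1.26-fold (peak CT9.55). The renal transport list did not pass against lists matched on mean expression (adjusted p = 0.642). Without the array at CT54, where pancreas markers reached a mean log2 of 7.47 against a tissue median of 6.06, 4837 genes were rhythmic.

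Lung had 4176 rhythmic genes, 155 of them above 1.5-fold. Spon2, a secreted matrix protein, varied 5.79-fold (4.90 to 6.85) with its peak at CT0.316 (SE 0.178 h, adjusted p = 2.02e-14). Fam124b varied 4.31-fold (3.31 to 5.62, peak CT22.2), the small nucleolar RNA Snord118 2.97-fold (1.68 to 5.25, peak CT4.81) and Aoc1, an enzyme that breaks down diamines, 2.80-fold (2.45 to 3.19, peak CT5.54). Snord118 did not pass in the rank test (adjusted p = 0.0972). Of 17 genes of the glucocorticoid response 15 were rhythmic (16 adjusted over the list alone, adjusted p = 6.31e-08), among them Fkbp5, a cochaperone of the glucocorticoid receptor (2.00-fold, 1.57 to 2.55, peak CT11.9), and the transcription factor Klf9 (1.46-fold, peak CT10.6). All 4 cold-inducible RNA binding genes were rhythmic (4 adjusted over the list alone, adjusted p = 0.00759), with Rbm3 at 1.41-fold and a peak at CT8.57. In the cytosolic ribosome list 10 of 18 were rhythmic (12 adjusted over the list alone, adjusted p = 0.00554) and peaked close together around CT6.76, with small waves such as Rps14 at 1.16-fold (1.10 to 1.22). No array stood apart, although hepatocyte markers ranged from a mean log2 of 5.68 to 8.11 (CT26) and red blood cell markers from 7.28 to 9.02 (CT48). The ribosome and cold-inducible lists did not pass against lists matched on mean expression (adjusted p = 0.625 and 0.185). All 4 cold-inducible members were rhythmic in lung, so that list could not have passed there.

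Heart had 1723 rhythmic genes, 122 of them above 1.5-fold. Tcap, which anchors titin at the edge of the sarcomere, varied 3.33-fold (2.88 to 3.85) with its peak at CT9.71 (adjusted p = 9.24e-12). Adam19, a membrane protease of heart development, varied 2.98-fold (2.63 to 3.38, peak CT22.5), Tmem171 2.75-fold (2.36 to 3.21, peak CT21.8) and the monooxygenase Fmo2 2.70-fold (2.35 to 3.10, peak CT14.9). Of 12 genes of angiogenesis and vascular tone 9 were rhythmic (9 adjusted over the list alone, adjusted p = 4.34e-07). The VEGF receptor Kdr varied 1.61-fold with a peak at CT0.455, its ligand Vegfa 1.33-fold with a peak at CT20.7, and Pik3r1, a subunit of PI3 kinase, 1.56-fold with a peak at CT14.6. Of 13 genes of cardiac electrophysiology 3 were rhythmic in heart (3 adjusted over the list alone), and no tissue passed the adjusted Fisher exact test, although 5 did at an unadjusted p under 0.05 and, with skeletal muscle markers as a covariate, aorta (adjusted p = 0.0415) and brown adipose (0.0198) passed. The aorta arrays also carried heart muscle markers, at a mean log2 of 10.1 against 12.1 in heart. These ranged from 8.58 to 10.96 over the aorta arrays and were not used as a covariate. Hepatocyte markers stood at a mean log2 of 10.56 on the heart array at CT26 against a tissue median of 6.202, and without that array 1640 genes were rhythmic.

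Aorta had 1015 rhythmic genes, 198 of them above 1.5-fold. Tshr, the receptor for thyrotropin, varied 3.91-fold (3.25 to 4.69) with its peak at CT23.8 (adjusted p = 2.05e-10). Angptl7, a secreted angiopoietin-like protein, varied 3.39-fold (2.42 to 4.74, peak CT16.3) and Cyp2b10, a drug-metabolizing cytochrome, 3.35-fold (2.66 to 4.23, peak CT17.7). The fast myosin heavy chain Myh2 had the largest fold, 6.30 (2.77 to 14.4, peak CT10.6), on arrays where skeletal muscle markers ranged from a mean log2 of 6.49 to 10.25. Itself 1 of these 12 markers, it had a fold of 2.27 with the mean of the other 11 as a covariate (adjusted p = 0.041) and missed with a straight line as covariate (0.0578). In cholesterol synthesis and uptake 10 of 16 genes were rhythmic (11 adjusted over the list alone, adjusted p = 9.98e-09) and their mean peak was CT20.9. In thermogenesis 5 of 12 were rhythmic (5 adjusted over the list alone, adjusted p = 0.000919), around CT6.42, on arrays where brown adipocyte markers had a mean log2 of 10.10 (SD 0.20), against 10.95 in brown adipose. Without the array at CT24, which held a neuron marker mean of 7.39 against a median of 6.10, 924 genes were rhythmic, and array weights gave 1879.

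Brown adipose had 3299 rhythmic genes, 638 of them above 1.5-fold. The largest folds belonged to sarcomere and muscle genes: Myot (probe set 10455461, chromosome 18 from 44334053 to 44355740) at 11.6 (3.68 to 36.7), the giant proteins Ttn 11.6 (3.46 to 38.6) and Neb 11.5 (3.52 to 37.3), and the calcium buffer Pvalb 11.5 (3.37 to 39.1), with peaks from CT22.7 to CT23.5. None of these 4 passed in the rank test (lowest adjusted p 0.0705, for Myot). On the same arrays the mean of 12 skeletal muscle markers ranged from log2 6.62 at CT36 to 11.73 at CT44. With that mean as a covariate Myot kept its call at a fold of 1.34 (adjusted p = 0.000978), the folds of Ttn and Neb were 1.07 and 1.07 (0.758 and 0.706), and 2010 genes were rhythmic. Pvalb, itself 1 of the markers, had a fold of 1.31 with the mean of the other 11 (0.131). Thermogenesis had 6 of 12 genes rhythmic (8 adjusted over the list alone, adjusted p = 0.0233) around CT7.81. Slc27a2, a fatty acid transporter and activating enzyme, varied 2.73-fold (2.46 to 3.02, peak CT8.01), and Ppargc1a, a coactivator of mitochondrial biogenesis, 2.02-fold (1.60 to 2.54, peak CT7.74). Collagen and matrix had 13 of 18 rhythmic (17 adjusted over the list alone, adjusted p = 2.12e-06), such as Serpinh1, the collagen chaperone (1.49-fold, peak CT20.7), and the crosslinking enzyme Lox (1.53-fold, peak CT22.5). With the muscle markers as a covariate 5 of the 18 collagen genes were rhythmic (adjusted p = 0.0707), and thermogenesis did not pass against lists matched on mean expression (adjusted p = 0.42). In the rank test 1968 genes were rhythmic, and 3613 were without the arrays at CT32 and CT64, which stood apart by hepatocyte and epididymis markers.

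White adipose had 966 rhythmic genes, 194 of them above 1.5-fold. Asb12, a subunit of ubiquitin ligases, varied 7.10-fold (4.89 to 10.3) with its peak at CT21.6 (adjusted p = 6.24e-07). Dtx4, an E3 ubiquitin ligase, varied 3.50-fold (2.98 to 4.11, peak CT22.9) and Thbs1, a matrix glycoprotein that restrains vessel growth, 3.04-fold (2.18 to 4.23, peak CT3.79). Bhmt, an enzyme of methionine metabolism, had a fold of 4.05 (2.06 to 7.95, peak CT22.2) that did not pass with epididymis markers as a covariate (2.66-fold, adjusted p = 0.124). Hepatocyte markers, which were not used as a covariate in this tissue, ranged from a mean log2 of 6.67 to 10.21. Of 16 genes of fatty acid synthesis 7 were rhythmic (10 adjusted over the list alone, adjusted p = 3.07e-05) with a mean peak at CT20.5. Epididymis markers ranged from a mean log2 of 5.03 to 11.59 and were high at CT38, CT50, CT58 and CT64, lung epithelium markers reached 10.50 at CT22, pancreas markers 7.95 at CT26 and kidney tubule markers 7.56 at CT32. Without these 7 arrays 637 genes were rhythmic, and array weights gave 2024.

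**Figure D2:**
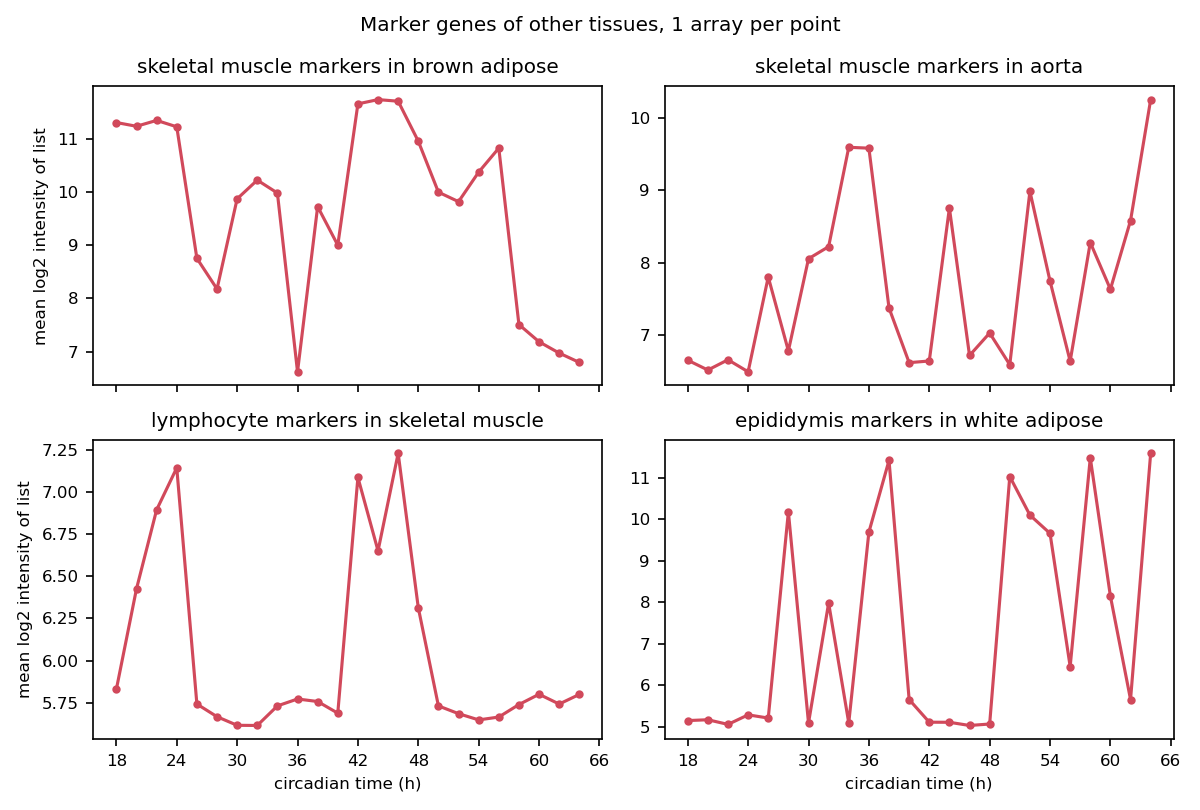
Mean log2 intensity of marker genes of other tissues against circadian time in hours, each point 1 array, in brown adipose, aorta, skeletal muscle and white adipose. Skeletal muscle markers in brown adipose run from 6.62 to 11.73, lymphocyte markers in skeletal muscle from 5.62 to 7.23, and epididymis markers in white adipose from 5.03 to 11.59.

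Skeletal muscle had 1020 rhythmic genes, 270 of them above 1.5-fold. The largest folds were those of Cxcl13, a chemokine that attracts B cells, at 12.3 (5.59 to 27.2, peak CT21.4), and Cd79b, a part of the B cell receptor, at 5.28 (2.92 to 9.53, peak CT21.3). The slow-fibre troponins Tnnc1 and Tnni1 followed at 4.82 (2.47 to 9.40) and 4.59 (2.27 to 9.27), with peaks at CT9.16 and CT9.31, and missed in the rank test (adjusted p = 0.179 and 0.223, as did Cd79b at 0.0514) and without the arrays that stood apart (0.1415 and 0.185). The mean of 8 lymphocyte markers ranged from log2 5.62 to 7.23 on these arrays and stood apart at CT22, CT24, CT42 and CT46. With that mean as a covariate Cxcl13 had a fold of 1.498 (adjusted p = 0.515), Tnnc1 and Tnni1 did not pass (0.782 and 0.854), and 395 genes were rhythmic. Cd79b, itself 1 of the markers, had a fold of 1.10 with the mean of the other 7 (0.745). The 4 arrays that stood apart lie between the middle and the end of the subjective night, around the peak of Cd79b. The covariate therefore overlaps with a 24 h wave and can take up part of a true one. Calls lost with it, here and below, do not by themselves show lymphocyte RNA. In muscle regulation and atrophy 8 of 14 genes were rhythmic (9 adjusted over the list alone, adjusted p = 9.37e-07). Fatty acid synthesis had 10 of 16 (13 adjusted over the list alone, adjusted p = 1.00e-08). With the lymphocyte covariate 1 of the 16 was rhythmic, and the list did not pass the Fisher exact test (adjusted p = 0.442). Adipocyte markers, which were not used as a covariate, ranged from a mean log2 of 7.80 to 9.64, highest at CT24. Without the 4 arrays that stood apart 722 genes were rhythmic, the rank test gave 556 and array weights 2085.

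Adrenal gland had 1174 rhythmic genes, 158 of them above 1.5-fold. Fabp7, a fatty acid binding protein, varied 3.56-fold (2.52 to 5.03) with its peak at CT2.14 (adjusted p = 0.000103), and Nrg4, a growth factor that adipose tissue secretes, 2.61-fold (2.13 to 3.19, peak CT10.4). Cbs, an enzyme of homocysteine metabolism, and Acot12, an acyl-CoA thioesterase of liver, had folds of 2.89 (1.64 to 5.09) and 2.48 (1.61 to 3.84) on arrays where hepatocyte markers ranged from a mean log2 of 5.96 to 12.27. With hepatocyte markers as a covariate Cbs missed (1.88-fold, adjusted p = 0.0585) and Acot12 passed (1.74-fold, 0.0347). Without the arrays that stood apart, which were not chosen by hepatocyte markers, neither passed (0.181 and 0.0912), nor did they in the rank test (0.340 and 0.229). Of 12 genes of steroid synthesis 3 were rhythmic (6 adjusted over the list alone), and the list did not pass the adjusted Fisher exact test in any tissue, with 1 tissue at an unadjusted p under 0.05, but with hepatocyte markers as a covariate 4 were rhythmic in adrenal gland and the list passed (adjusted p = 0.00603). The 3 were Mrap, which carries the corticotropin receptor to the cell surface (1.62-fold, 1.44 to 1.83, peak CT20.0), the receptor itself, Mc2r (1.27-fold, 1.15 to 1.40, peak CT21.0), and the cholesterol importer Scarb1 (1.31-fold, 1.17 to 1.47, peak CT17.0), of which Scarb1 did not pass without the arrays that stood apart (adjusted p = 0.0981) and Mc2r not in the rank test (0.0544). Heat shock had 11 of 16 genes rhythmic (12 adjusted over the list alone, adjusted p = 1.60e-09), close together around CT18.9. Without the arrays at CT28, CT50 and CT52, of which CT28 and CT52 stood apart by skeletal muscle markers and CT50 by its correlation to the others, 743 genes were rhythmic, quantile normalization gave 1784 and array weights 3153.

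Among rhythmic genes the waves were smallest in cerebellum and brainstem by median fold. That median also depends on the smallest wave a tissue can call, so part of the order can come from detection. The smallest called fold was 1.05 in cerebellum and brainstem and 1.10 in white adipose, but 1.04 in kidney, liver and lung. Cerebellum had 1094 rhythmic genes with a median fold of 1.13 (brainstem 1.145, hypothalamus 1.195), and 13 exceeded 1.5-fold. The glucocorticoid target Zbtb16 varied 1.98-fold there (1.61 to 2.44, peak CT13.5), Sostdc1, an inhibitor of BMP and Wnt signalling, 1.79-fold (1.41 to 2.27, peak CT5.55), the carbonic anhydrase Car12 1.76-fold (1.37 to 2.27, peak CT6.93), and Fabp7, a marker of radial glia and astrocytes, 1.57-fold (1.47 to 1.68, peak CT4.24). Car12 did not pass in the rank test (adjusted p = 0.0629), which called 643 genes in cerebellum. Of 15 endoplasmic reticulum stress genes 12 were rhythmic in cerebellum (13 adjusted over the list alone, adjusted p = 1.04e-11) around CT19.4. No cerebellum array stood apart.

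Brainstem had 953 rhythmic genes, 23 of them above 1.5-fold. The stress-induced kinase Sgk1 varied 1.88-fold (1.47 to 2.40, peak CT11.8), Ppbp, a platelet chemokine, 1.89-fold (1.478 to 2.413, peak CT0.633) and the adhesion protein Mpzl2 1.69-fold (1.49 to 1.92, peak CT12.8). Cbln3, a gene of cerebellar granule cells, had the largest fold, 2.33 (1.51 to 3.58, adjusted p = 0.0405), on arrays where cerebellar neuron markers ranged from a mean log2 of 7.78 to 9.46. It did not pass in the rank test (adjusted p = 0.271), nor did Ppbp (0.222), and that test called 543 genes. Of 17 glucocorticoid response genes 13 were rhythmic (15 adjusted over the list alone, adjusted p = 1.01e-12) around CT12.4. Without the array at CT36, where pituitary markers reached 6.54 against a median of 5.45, 785 genes were rhythmic.

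Hypothalamus had 359 rhythmic genes, the fewest of the 12 tissues, and 13 exceeded 1.5-fold. Fabp7 varied 1.91-fold (1.78 to 2.04) with its peak at CT3.79 (SE 0.199 h, adjusted p = 3.56e-12). Sgk1 varied 1.83-fold (1.39 to 2.42, peak CT11.4), Zbtb16 1.81-fold (1.46 to 2.25, peak CT12.9) and the oligodendrocyte gene Opalin 1.65-fold (1.41 to 1.93, peak CT5.58). Heat shock and endoplasmic reticulum stress had 8 of 16 and 8 of 15 genes rhythmic (15 and 12 adjusted over the list alone, adjusted p = 1.88e-09 and 1.06e-09) around CT20.6 and CT20.5. Leaving out 1 array moved the count from 219, without CT54, to 444, without CT18, with 229 without CT28 and 231 without CT52. Without the arrays at CT18 and CT36, which stood apart by their correlation to the others, 670 genes were rhythmic, more than the 637 of white adipose under the same rule, so the lowest rank is not kept. Array weights gave 1121.

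**Figure D3:**
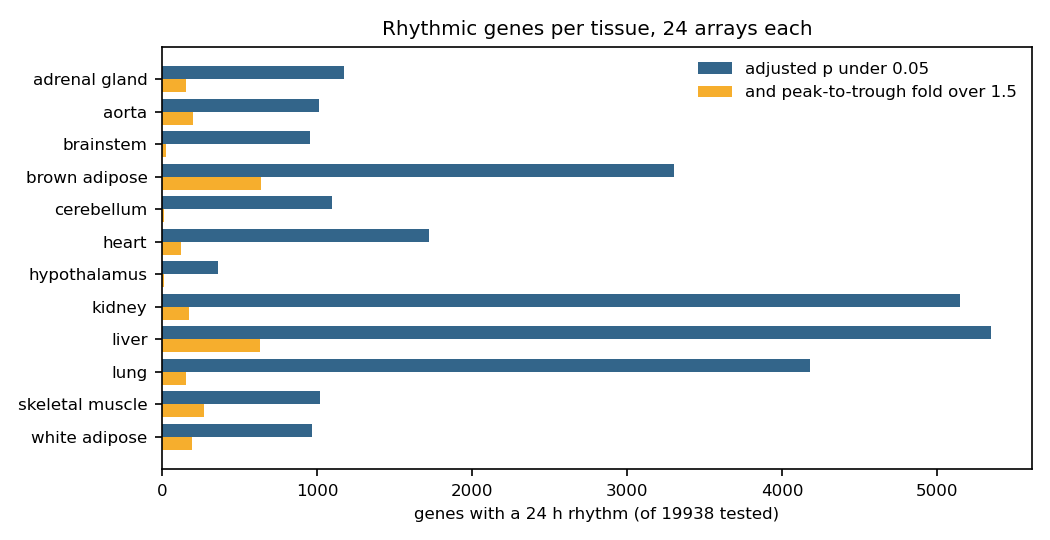
Number of genes with a 24 h rhythm per tissue (adjusted p under 0.05, of 19938 tested, 24 arrays each) and, in the second bar, those whose peak-to-trough fold also exceeds 1.5. Counts run from 359 in hypothalamus to 5343 in liver.

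Peak times gathered before the subjective night ended in most tissues. Of the rhythmic genes of liver, 47.3% peaked between CT18 and CT24, as did 48.2% in brainstem, 43.1% in brown adipose, 41.8% in kidney, 36.9% in white adipose and 35.3% in cerebellum. The busiest 6 h began at CT16 in adrenal gland (43.6%), heart (34.7%) and hypothalamus (41.8%) and at CT20 in skeletal muscle (58.5%). Cerebellum had a second group of peaks in the day, with its fullest 2 h from CT8 to CT10 (160 genes) and 52.5% of its genes between CT0 and CT12. Aorta and lung differed, with 40.2% of aorta genes between CT4 and CT10 and 36.2% of lung genes between CT6 and CT12. These are descriptions of selected genes, which are not independent of each other. The second day repeated the first: across rhythmic genes the Pearson correlation of amplitudes on the 2 days ran from 0.669 in hypothalamus to 0.887 in brown adipose, and the median difference of peak times from 0.952 h in liver to 1.45 h in skeletal muscle. Genes are not independent replicates, and rhythmic genes were selected on both days.

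**Figure D4:**
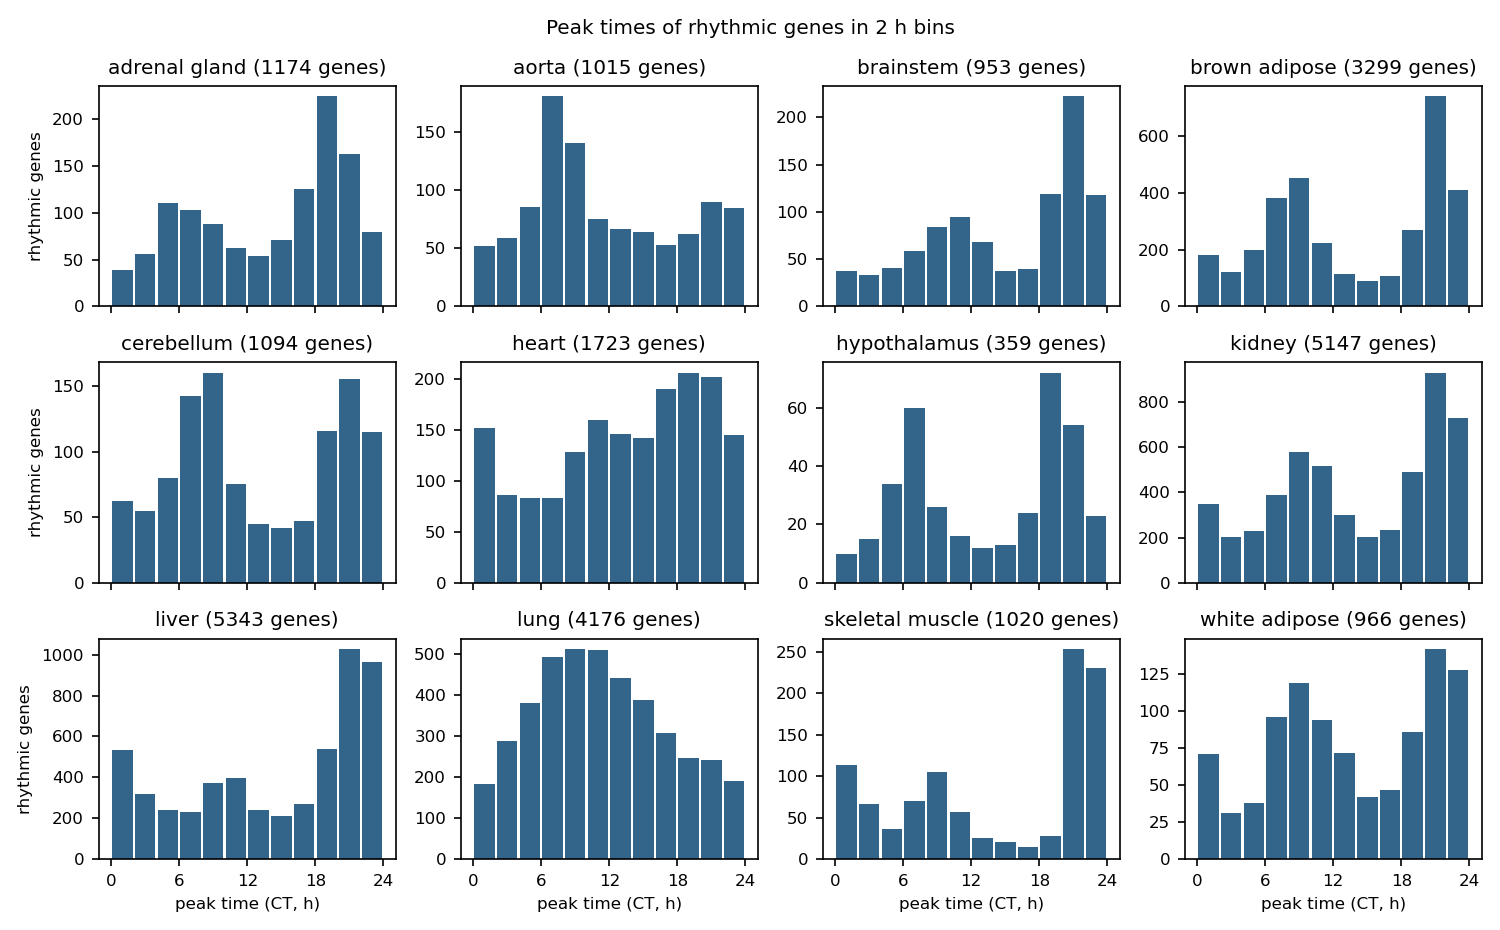
Number of rhythmic genes per 2 h bin of peak time (CT in hours), 1 panel per tissue. Liver, kidney and brown adipose have their highest bar from CT20 to CT22, with 1027, 929 and 741 genes, while lung has its highest from CT8 to CT10, with 511.

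Across tissues, 11734 genes (58.9%) were rhythmic in at least 1 of the 12, and 14 were rhythmic in all 12. Of these 14, 12 belong to the fixed clock lists: Arntl, Bhlhe41, Ciart, Nr1d1, Nr1d2, Per1, Per2, Per3, Dbp, Tsc22d3, Tspan4 and Usp2. Those lists name genes already assigned to the clock, so this share is a description. The other 2 were Tns2, which links integrins to the cytoskeleton (probe set 10427095, chromosome 15 from 102098475 to 102116401), with a mean peak at CT8.70 and folds from 1.20 in brainstem to 1.98 (1.74 to 2.25) in brown adipose, and Rhoj, a GTPase of endothelial cells (probe set 10396476, chromosome 12 from 75308313 to 75401455), with folds from 1.16 in brainstem to 1.41 (1.32 to 1.51) in heart around CT0.0122. Of the 15 genes that passed in 11 tissues, 4 were the clock genes Clock, Cry1, Tef and Hlf, and 10 others were Fmo2 (mean peak CT14.7), Dtx4 (CT23.2), Lonrf3 (CT18.5), Coq10b, a carrier of coenzyme Q (CT10.7), Maco1 (CT13.1), Gstt2, a glutathione transferase (CT8.41), the calcium-binding chaperone Calr (CT21.7), Fkbp5 (CT13.3), the cold-inducible RNA binding protein Cirbp (CT6.54) and Slc16a1. Slc16a1 changed its timing most, from CT22.1 in kidney to CT4.43 in brainstem, CT9.38 in lung and CT17.2 in heart (interaction adjusted p = 3.63e-52). Of all rhythmic genes 4996 (42.6%) passed in exactly 1 tissue, and 2815 of those also passed the test that rhythms differ. The rank test gave 10 genes rhythmic in all 12 tissues: Tns2 missed in hypothalamus (adjusted p = 0.0685) and brainstem (0.0527), Rhoj in hypothalamus (0.0603), brainstem (0.0696) and liver (0.0636), Bhlhe41 in brainstem (0.199) and Tspan4 in cerebellum (0.0557). Rhoj also missed in white adipose without the arrays that stood apart (0.114), and array weights gave 24 such genes. Tns2 in hypothalamus (0.0485) missed too with all probe sets (0.0505), a straight line (0.0838) and the 12 h pair (0.0519). Some of these 10 genes of 11 tissues also lost calls under alternatives: Calr in 4 tissues, Gstt2 in 3, Coq10b, Fkbp5 and Cirbp in 2 and Dtx4, Lonrf3 and Slc16a1 in 1, while Fmo2 and Maco1 lost none.

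Rhythms differed between tissues for 9883 genes (49.6%), of which 8815 were rhythmic in at least 1 tissue. Simulated data with 200 changed genes gave 216 false calls in this test, more than an adjusted p under 0.05 should allow. The test uses 1 pooled spread, and the share of false calls among the 9883 genes is not known. In 1424 combinations of a gene with a pair of tissues, covering 974 genes, both tissues were rhythmic with peaks at least 10 h apart. These counts hold only combinations that also passed the test of difference for that pair. The 8 with the largest waves were all muscle genes. Myh2 peaked at CT10.6 in aorta and CT22.2 in brown adipose. The slow-fibre genes Tnnc1, Tnni1, Tnnt1, Myh7, Myl2 and Myl3 and the calcium store protein Casq2 peaked between CT21.4 and CT21.9 in brown adipose and between CT8.34 and CT9.31 in skeletal muscle, with folds in brown adipose from 2.13 (1.61 to 2.82) for Casq2 to 8.72 (3.64 to 20.9) for Myh7. With the marker covariates described above, these 7 genes did not pass in skeletal muscle (adjusted p from 0.74 to 0.854), while in brown adipose Tnnc1 and Myl3 missed (0.0567 and 0.0544) and the other 5 passed with smaller folds (Myh7 2.26, Tnnt1 2.83, Myl2 2.38, Tnni1 2.23, Casq2 1.66). In the rank test these 7 missed in skeletal muscle, and Tnnc1 (0.241), Tnnt1 (0.128), Myl2 (0.0705) and Myl3 (0.159) missed in brown adipose. Myh2, with its own values left out of the covariate, passed in aorta (0.041) and not in brown adipose (0.0915). Among pairs of tissues, cerebellum and hypothalamus differed in rhythm for 7 genes, brainstem and cerebellum for 18, and liver and white adipose for 5320. These tests share the pooled spread, which is too strict for tissues of small spread and too lenient for those of large spread. The median residual SD was 0.0688 in cerebellum, 0.0816 in brainstem and 0.0842 in hypothalamus, against 0.0994 in liver and 0.134 in white adipose. Part of the contrast between pairs can therefore come from the test.

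By function, 129 of 324 pairs of list and tissue held more rhythmic genes than the rest of the genome, and in 100 of these the mean profile of the list was also rhythmic. Besides the clock lists, the widest was the glucocorticoid response, in 11 tissues, with mean peaks of its rhythmic members from CT7.52 in adrenal gland to CT13.2 in cerebellum. That list shares Per1 with the core clock list and Tsc22d3 with the clock output list, both rhythmic in all 12 tissues. It was not tested without them, here or against the matched lists below. Heat shock genes passed in 10 tissues and peaked close together in each, from CT17.3 in liver to CT20.6 in hypothalamus. Endoplasmic reticulum stress passed in 9 tissues, latest in heart, where 11 of 15 genes (13 adjusted over the list alone) had a mean peak at CT23.5. Cholesterol synthesis also passed in 9 tissues, with mean peaks at CT20.9 in aorta and CT23.9 in liver but CT6.60 in cerebellum and CT5.08 in brainstem, both of which missed against lists matched on mean expression (0.103 and 0.273). Fatty acid synthesis passed in 9, cold-inducible RNA binding in 9, collagen and matrix in 8 and angiogenesis in 8. Immediate early genes passed in no tissue by the Fisher exact test, adjusted or at an unadjusted p under 0.05, with at most 6 of 18 rhythmic (7 adjusted over the list alone), in lung, where Nr4a1, a nuclear receptor induced within minutes of a stimulus, varied 1.60-fold (1.28 to 1.98, peak CT7.60, adjusted p = 0.247 in the rank test). Abundant genes were rhythmic more often than dim ones, and against random lists matched on mean expression 72 pairs passed, among them 12 tissues for each clock list, 11 for the glucocorticoid response, 9 for heat shock, 6 for endoplasmic reticulum stress, 7 for fatty acid synthesis, 4 each for collagen and angiogenesis, 3 for cholesterol synthesis and 0 for cold-inducible RNA binding (lowest adjusted p 0.185). All 4 members of the cold-inducible list were rhythmic in kidney, liver and lung, so the matched test could not pass there. Its misses are therefore no evidence against the list, whose mean profile was rhythmic in 12 tissues. Among genes above the tissue median, 85 pairs passed.

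Waves of 12 h were found mainly in skeletal muscle, with 1393 genes, and brown adipose, with 963. In skeletal muscle the first genes were the olfactory receptors Olfr639 (1.26-fold, mean log2 5.07) and Olfr1537 (1.97-fold, mean log2 6.196), the predicted gene Gm6471 (1.49-fold) and Lyz1, a lysozyme of epithelia and myeloid cells (1.66-fold), each with an adjusted p of 0.00663. Of the 1393 genes, 64.2% lay below the tissue median and 351 were olfactory or vomeronasal receptors, which these tissues are not known to use. With only genes above the median tested, 63 passed, quantile normalization left 241, and 386 passed without the arrays that stood apart. In brown adipose, Myh2 had a 12 h wave of 6.64-fold (adjusted p = 0.000721) and Myot of 8.53-fold (0.00331), on the arrays whose muscle markers varied, and with those markers as a covariate 1 gene, the muscle filamin Flnc, passed (chosen after its value was seen). Liver had 65 genes and lung 12, while brainstem, heart and kidney had 1 each: Cldn5, Ciart and Cyp1b1, named after their values were seen. Ciart, a repressor within the clock, had a 12 h component of 2.47-fold in heart (adjusted p = 0.000479). By limma, 0 genes passed in adrenal gland, aorta, cerebellum, hypothalamus and white adipose, with 1353, 1175, 727, 691 and 2156 at an unadjusted p under 0.05. In adrenal gland 62 passed with only genes above the median tested and 40 after quantile normalization. The counts of liver and brown adipose also moved by more than 1.5-fold under alternatives, which are listed at the end.

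Trends over the 2 days were found in kidney, where 217 genes rose and 375 fell, in skeletal muscle, where 8 rose and 338 fell, and in brainstem, where 79 rose and 4 fell. In kidney the small nucleolar RNA Snora23 rose by 0.26 log2 units per day (SE 0.04, adjusted p = 0.00377) and the superoxide dismutase Sod1 by 0.10 (SE 0.02, adjusted p = 0.00603). Srsy fell by 0.88 per day (SE 0.14, adjusted p = 0.00603) and the olfactory receptor Olfr483 fell by 0.37 (SE 0.06, adjusted p = 0.00742). The 4 falling genes of brainstem were Srcin1, Ptprs, Nacc2 and Mthfsd, named after their values were seen. By limma, 0 genes passed in the other 9 tissues, with counts at an unadjusted p under 0.05 of 1192 in adrenal gland, 2370 in aorta, 1142 in brown adipose, 2829 in cerebellum, 2838 in heart, 2265 in hypothalamus, 646 in liver, 831 in lung and 3739 in white adipose. A random order of the skeletal muscle time points gave 613 genes with a trend, more than the 346 of the real order. Kidney had 288 such genes without the array at CT54 and 1328 with array weights, brainstem had 230 after quantile normalization, and white adipose had 1881 with array weights.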

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

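The tests with marker covariates, and of spread, arrays that stand apart and wave size in hypothalamus, were chosen only after the results were seen, and the planned counts of genes above the tissue median had been seen before they were used as tests here. The direction test in brown adipose, the shared waves of dim genes and dim probe sets in skeletal muscle and the shuffles were written down before their values were seen.

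Rhythms differed between tissues by the interaction test for 9883 genes, with adjusted p-values of 3.17e-74 for Arntl, 2.9e-59 for Nr1d1, 4.58e-51 for Dbp and 9.64e-38 for Cry1. By the same test for pairs of tissues, Myh2 peaked 11.61 h apart in aorta and brown adipose. Between brown adipose and skeletal muscle the distance was 11.69 h for Tnnc1, 11.64 h for Tnni1, 11.1 h for Myh7, 11.8 h for Tnnt1, 11.26 h for Myl2, 11.24 h for Myl3 and 10.99 h for Casq2. Signal in the data outside the comparisons lay in the probe sets without a single gene symbol, of which 2204 of 13767 were rhythmic in at least 1 tissue and 5 in at least 9.

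The 963 genes with 12 h waves in brown adipose may come from skeletal muscle RNA in the samples. With the mean of 12 skeletal muscle markers as a covariate, 1 gene passed. Myh2, 1 of these markers, had a 12 h wave itself, so the covariate could also take up a 12 h wave of the tissue. Of 951 genes outside the markers, 80.02% moved with the marker mean toward their skeletal muscle level, against 58.16% of all genes, a share between the limits written for a yes and a no and open to the normalization of each tissue apart. Dim probes do not account for the waves, since 955 genes passed among those above the tissue median. Why muscle RNA would vary over these arrays was not tested, and a 12 h rhythm of brown adipose itself stays open.

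The 1393 genes with 12 h waves in skeletal muscle lay mostly among dim genes, and noise or shifts of dim probes may account for part of them. Tested alone, genes above the median gave 63, although 498 of them passed in the test of all genes. A 12 h wave in the mean of the dimmest genes (permutation p = 0.00049) decides nothing, since that mean holds called genes. Among 3442 dim probe sets outside the tested genes the wave did not pass (permutation p = 0.2052), a no by the limit written beforehand. Its peak lay at 1.93 h, against a mean of 0.686 h for the 12 h genes under the median. A test that does not pass cannot exclude a shift of dim probes. Quantile normalization, which evens out such shifts between arrays, lowered the count of 12 h genes, as given above. With the lymphocyte marker mean as a covariate 1355 genes passed, which argues against lymphocyte RNA in proportion to these markers. Far fewer passed without the 4 arrays that stand apart, each with raised lymphocyte markers, as given above. Lymphocyte RNA therefore stays open for part of the waves. A 12 h rhythm of muscle itself was not tested and stays open.

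Hypothalamus had the fewest rhythmic genes, 359, a rank it does not keep without the arrays that stand apart (670, against 637 in white adipose and 785 in brainstem). Those arrays do not account for the difference from liver, which then had 7.937 times as many. Smaller waves are a candidate explanation of the difference from liver, with a median core clock fold of 0.3104 times that of liver, but not of that from brainstem (0.9821 times). The residual SD among genes above the median was 0.8017 times that of liver, which argues against a larger spread between arrays there, and 1.349 times that of brainstem but 1.032 times over all genes, so spread cannot be told apart from other explanations there. A difference in the biology of this region was not tested and stays open.

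Chance can be excluded for these counts only to the level that 100 orders of the time points allow: the real order stood first (1) for each count but that of skeletal muscle trends, which stood at 2. The real count of 24 h genes and the highest of any other order were 1174 and 964 in adrenal gland, 1015 and 1 in aorta, 953 and 3 in brainstem, 3299 and 10 in brown adipose, 1094 and 4 in cerebellum, 1723 and 1 in heart and 359 and 3 in hypothalamus. They were 5147 and 4 in kidney, 5343 and 69 in liver, 4176 and 2 in lung, 1020 and 585 in skeletal muscle, 966 and 245 in white adipose, and 11734 and 964 for at least 1 tissue. For 12 h waves they were 1393 and 4 in skeletal muscle, 963 and 3 in brown adipose, 65 and 2 in liver and 12 and 2 in lung. For trends they were 592 and 1 in kidney and 83 and 30 in brainstem. In skeletal muscle there were 346 trends and 613 in another order. The margin is also narrow in adrenal gland, where the count without the arrays that stand apart (743) lies below 964 and was not compared with orders of its own. Shuffled tissue labels gave at most 2 genes with different rhythms, against 9881 in the centred data. These shuffles mix tissues of unlike spread, so they cannot show false calls that come from the pooled spread.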

How the results depend on the processing

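Leaving out arrays that stand apart, the marker covariates (also with a marker gene left out of its own covariate) and the restriction to rhythmic clock genes were chosen only after the results were seen, and the other tests were planned. For each change below the cause was not tested.

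Array weights gave 3153 rhythmic genes in adrenal gland, 1879 in aorta, 1121 in hypothalamus, 2085 in skeletal muscle and 2024 in white adipose, 24 genes in all 12 tissues, and trends for 1328 genes in kidney and 1881 in white adipose. The other 18 of 26 results held. Quantile normalization gave 1784 rhythmic genes in adrenal gland, 12 h waves for 40 genes in adrenal gland, 99 in liver and 241 in skeletal muscle, and trends for 1 gene in aorta (Hipk2, named after its value was seen) and 230 in brainstem, while 32 of 38 results held. The rank test gave 543 rhythmic genes in brainstem, 1968 in brown adipose, 643 in cerebellum and 556 in skeletal muscle, and 10 of 14 held. With only genes above the median, 12 h waves numbered 62 in adrenal gland, 122 in liver and 63 in skeletal muscle, and 85 pairs of list and tissue passed, and 24 of 28 held. Random lists matched on mean expression left 72 pairs.

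Without the arrays that stand apart there were 743 rhythmic genes in adrenal gland, 670 in hypothalamus and 637 in white adipose, 12 h waves for 582 genes in brown adipose and 386 in skeletal muscle, and 288 trends in kidney, and 34 of 40 results held. Marker covariates left 2010 rhythmic genes in brown adipose and 395 in skeletal muscle and 1 gene with a 12 h wave in brown adipose (Flnc), and 12 of 15 held. Markers such as Cd79b in skeletal muscle and Pvalb in brown adipose had 24 h waves themselves. Such a covariate can therefore also take up part of a true wave. All probe sets, a straight line, the 12 h pair, the replicate block and the spread per tissue moved no gene count by more than 1.5-fold. The restriction to rhythmic clock genes kept the calls on timing, while offsets that did not pass moved from -0.7018 to 0.0697 h in hypothalamus and from 0.01206 to 0.3105 h in brainstem.

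Leaving out each array in turn moved the hypothalamus count from 219 to 444, and no other tissue by more than 1.5-fold. Leaving out each clock gene moved the lung offset from -0.3552 to -0.2284 h and ended its call in 8 of 12 cases, and moved the skeletal muscle offset from -1.3585 to -0.9018 h, which passed in 2 of 12 cases.

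Of 591 results for named genes, 60 lost their call or weakened in the rank test, 25 without the arrays that stand apart, 19 with a straight line, 3 with the 12 h pair, 2 with all probe sets and 23 when single arrays were left out, and of 278 with a marker covariate 31 did. The 591 include results that did not pass in the main test and had no call to lose. A result was counted as turned only if it passed in both settings and its peak moved over 6 h, and none was. Lost calls could not count as turned, and some of their peaks lay far from those given above. With the gene left out of its marker covariate, Pvalb peaked at CT5.2 in brown adipose and Cd79b at CT2.8 in skeletal muscle. Array signal includes background, which compresses the folds of dim genes and limits what a missing call there means.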

Other observations

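The comparison of shared rhythms below was chosen only after the counts were seen, and no other tests were added.

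The 3 brain regions shared many of their rhythmic genes. The ratio to independent sets can be larger where sets are small, so the percent of the smaller set is given too. The labels do not say whether the organs of a time point come from the same mice, and if they do, differences between mice add to these numbers. Brainstem and hypothalamus had 178 in common, 49.6% of the smaller set and 10.4 times the 17.2 that independent sets would share, and the median difference of their peaks was 0.767 h. Brainstem and cerebellum had 292 (30.6%, 5.58 times), and cerebellum and hypothalamus 145 (40.4%, 7.36 times). Genes rhythmic in both brainstem and hypothalamus include the glucocorticoid targets Sgk1 and Zbtb16 and the glial gene Fabp7. Aorta and white adipose had 321 in common (33.2%, 6.53 times, median difference 1.29 h), adrenal gland and aorta 294 (29.0%, 4.92 times) and aorta and brown adipose 738 (72.7%, 4.39 times), the highest percent of any pair, and 95.5% of these 738 peaked within 4 h. The aorta arrays carried brown adipocyte markers at a mean log2 of 10.10, close to the 10.95 of brown adipose.

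Kidney and liver had the largest shared set, 2322 genes (45.1% of the smaller set, 1379 for independent sets), of which 69.5% peaked within 4 h of each other. Liver and lung had 1671 in common with a median difference of 3.69 h and 52.7% within 4 h. Genes are not independent of each other, so these shares are descriptions.

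The probe sets without a single gene symbol were most often rhythmic in liver, with 1458, then kidney (519), lung (393) and brown adipose (352), and least often in hypothalamus (4). The 5 that were rhythmic in at least 9 tissues are 10345675 and 10556487 in 11 tissues each and 10409276, 10526363 and 10557843 in 9 each. They carry no symbol in the annotation used here, and their transcripts were not analysed here.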
